A study of Mus musculus with 8 samples.

How the data were processed

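Gene expression was measured by RNA sequencing in 8 mouse skin libraries, 2 from mice given phosphate-buffered saline (PBS), 3 from mice given bleomycin and 3 from mice given celastrol. Per the labels' protocols, the animals were male C57BL/6J mice treated from 6 weeks of age, and total RNA was taken from skin homogenates after 21 days. PBS (0.1 mL) and bleomycin (0.1 units) were injected under the skin, and celastrol was injected into the peritoneum daily at 1 or 2 mg/kg. The labels do not say which dose a given celastrol mouse received, nor whether celastrol mice also received bleomycin.

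The deposited table holds a normalized signal per gene and library, on a linear scale, for 24612 genes in 8 libraries. The authors scaled estimated gene counts by a size factor per library, in the poscounts form of DESeq2, per the file headers and the submitters' processing notes. Those notes name Partek 10.0.22, STAR 2.7.3a, DESeq2 and the mm10 build, but not the settings of the aligner, the counter, the gene annotation or the use of strand. Values below 1000 reads fell within 0.03 reads of a whole number of reads in 58.9% to 67.6% of genes per library, so the raw counts could not be recovered. No gene had a maximum under 10.3 over the libraries, a floor that the labels do not mention. The library sums lay between 22900000 and 26400000. From the value of a single read, the depth was estimated at 33600000 reads for PBS 2, 21700000 for PBS 3, 33300000 for Bleomycin 2, 18500000 for Bleomycin 3, 31600000 for Bleomycin 4, 15100000 for Celastrol 2, 14900000 for Celastrol 3 and 37100000 for Celastrol 5. Positions come from the table, and 23752 genes matched GENCODE release M21 by symbol, chromosome, strand, start and end.

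The test was limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend) on log2 of the deposited value plus a pseudocount of 1. All 8 libraries entered a single fit, so that the groups shared an estimate of the spread, and no covariate was used. Genes with a value of at least 10 in at least 2 libraries were tested, which kept 23185 and removed 1427. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. DESeq2 and edgeR were not used for testing, since the values are not counts.

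The groups, the tests, 38 gene lists, the rule for the genes to be named and most alternatives were fixed before the data were examined. The lists cover matrix genes, signalling, cell types and stress responses, and 920 of their 988 members were measured. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 38 lists. They were tested again with an estimated correlation and with fry, which asks whether the genes of a list move 1 way on balance and makes no comparison with other genes. Member counts are given over all genes, and those adjusted over the list alone are given for called lists where any member passed.

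Named genes followed a rule with 3 parts. The first took, per comparison, up to 10 genes with the highest and up to 10 with the lowest log2 fold change among genes past the threshold, with a mean value of at least 50 and no overlap between the libraries of both groups. Predicted genes (symbols of the Gm and Rik kinds), mitochondrial and ribosomal protein genes were left out there. Where fewer passed, the genes with the smallest p in that direction under the same conditions filled the places. The next part took the up to 4 members with the smallest p of each list called, and of the collagen, matrix glycoprotein, YAP/TAZ, TGF-beta and myofibroblast lists in every comparison, of which the text gives those with the smallest p. The last part was Col1a1, Col1a2, Col3a1, Ccn2, Acta2, Ccn1 and Tgfb1. Other genes are said to have been chosen after their values were seen.

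Whether celastrol libraries differed in the genes that separate bleomycin from PBS was measured with held-out libraries. For each bleomycin library in turn, the 200 highest and the 200 lowest genes were chosen from the other bleomycin libraries, and the celastrol mean was compared with the library left out of the choice. Chance similarity from the shared PBS libraries was simulated with 100 random draws of unchanged groups, with each gene drawn independently. Where every library of a group was at 0, the fold is a bound at a floor of 3 reads per library. Where a group held 1 to 3 reads, the ratio is given with a 95% counting interval. Bounds and intervals cover counting error only.

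The procedure was tested on simulated data with changes of known size, run on 22304 genes. Changes were placed in 50 genes per fold and comparison, all with a mean value of at least 50, and genes were drawn independently. For bleomycin against PBS, 24% of genes changed 2-fold, 58% changed 4-fold, 80% changed 8-fold and 82% changed 16-fold were recovered, with 5 false calls among 127. For celastrol against bleomycin the shares were 12%, 66%, 82% and 84%, with 7 false calls among 129. Both camera versions called 0 of 38 random lists. Because the simulated genes were independent, this does not test lists whose genes move together.

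The alternatives chosen beforehand were a pseudocount of 0.5 or 5, no filter, a minimum of 50, TMM scaling (own code) or quantile normalization on top of the deposited values, only the groups compared in the fit, library weights, a robust spread, the replicate number as a block, 100 or 500 genes in the held-out measure, and each library left out in turn. Alternatives chosen after seeing the data were a loess correction for transcript GC content (values for 22416 genes, 96.7% of those tested), leaving out PBS 2 and Bleomycin 2, and leaving out Bleomycin 3, Celastrol 2 and Celastrol 3. The last of these leaves Celastrol 5 as the only celastrol library. Replicate numbers do not mark shared animals, litters or days in the labels, so the block was kept as an alternative. Gene spans in the deposited table were not used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.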

Results

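Skin RNA was profiled in 2 PBS, 3 bleomycin and 3 celastrol libraries, each from a mouse sampled at 21 days. Bleomycin is a DNA-damaging agent that is injected into mouse skin to model the fibrosis of systemic sclerosis, and celastrol is a plant triterpenoid that the study examined as an antifibrotic compound. Values are the deposited normalized values, given as mean ± SD with the number of libraries, and changes are on the log2 scale with the standard error (SE) of the limma fit. Estimated depth differed within groups, as between Celastrol 3 and Celastrol 5. Principal component 1 held 32.7% of the variance and set Celastrol 2 apart at a score of 237.5, while the other libraries lay between -57.3 and -3.63.

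The comparison of bleomycin with PBS asked which genes bleomycin injection changed in skin. Interferon-stimulated genes, p53 targets, myeloid genes and stress genes of the epidermis were higher, and collagens, other matrix genes and fibroblast markers were lower, by camera at its preset correlation. With an estimated correlation 1 of the 19 list calls held, that of the p53 list, and the collagens had an adjusted p = 0.257. Of 23185 genes tested, 157 passed in limma, 105 higher and 52 lower, with a smallest adjusted p of 0.000399. Genes called as lower numbered 6 without PBS 2, 0 without PBS 3, 7 without Bleomycin 3 and 1 without Bleomycin 4. Zbp1, a sensor of unusual nucleic acids, rose from 186 ± 5.35 (n = 2) to 959 ± 213 (n = 3). Col1a2, a chain of type I collagen, fell from 169740 ± 97430 (n = 2) to 10517 ± 11520 (n = 3).

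Interferon-stimulated genes were the list with the smallest camera p. Of 39 members measured, 15 rose over all genes, 0 fell and 24 did not pass, and 30 rose adjusted over the list alone. The list median was 1.48 (camera adjusted p = 1.94e-51, and adjusted p = 0.0651 with an estimated correlation). Zbp1 rose by 2.34 ± 0.25 (SE) (adjusted p = 0.00506) and the oligoadenylate synthetase-like gene Oasl2 by 2.28 ± 0.25 (adjusted p = 0.00506). Ifit3 and Ifit1, which restrict viral RNA, rose by 2.73 ± 0.32 (adjusted p = 0.00613) and 2.33 ± 0.29 (adjusted p = 0.0101).

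The p53 and DNA damage list was the list that both camera versions called. Of 30 members, 8 rose, 0 fell and 22 did not pass, and 13 rose adjusted over the list alone. Its median was 0.86 (camera adjusted p = 2.7e-17, and adjusted p = 0.00794 with an estimated correlation). The proapoptotic gene Pmaip1 rose by 2.10 ± 0.29 (adjusted p = 0.0138), from 243 ± 1.25 (n = 2) to 1077 ± 327 (n = 3). The nuclease gene Aen rose by 1.42 ± 0.22, Mdm2, the ubiquitin ligase that restrains p53, by 1.05 ± 0.17, and the kinase gene Plk2 by 1.06 ± 0.18, with adjusted p of 0.0209, 0.0274 and 0.031. The cell cycle list had a median of 0.34 with 0 of 40 members past the threshold (camera adjusted p = 4.19e-06, and adjusted p = 0.357 with an estimated correlation). Its smallest single adjusted p was 0.101, for the ribonucleotide reductase gene Rrm1 at 0.83.

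**Figure D1:**
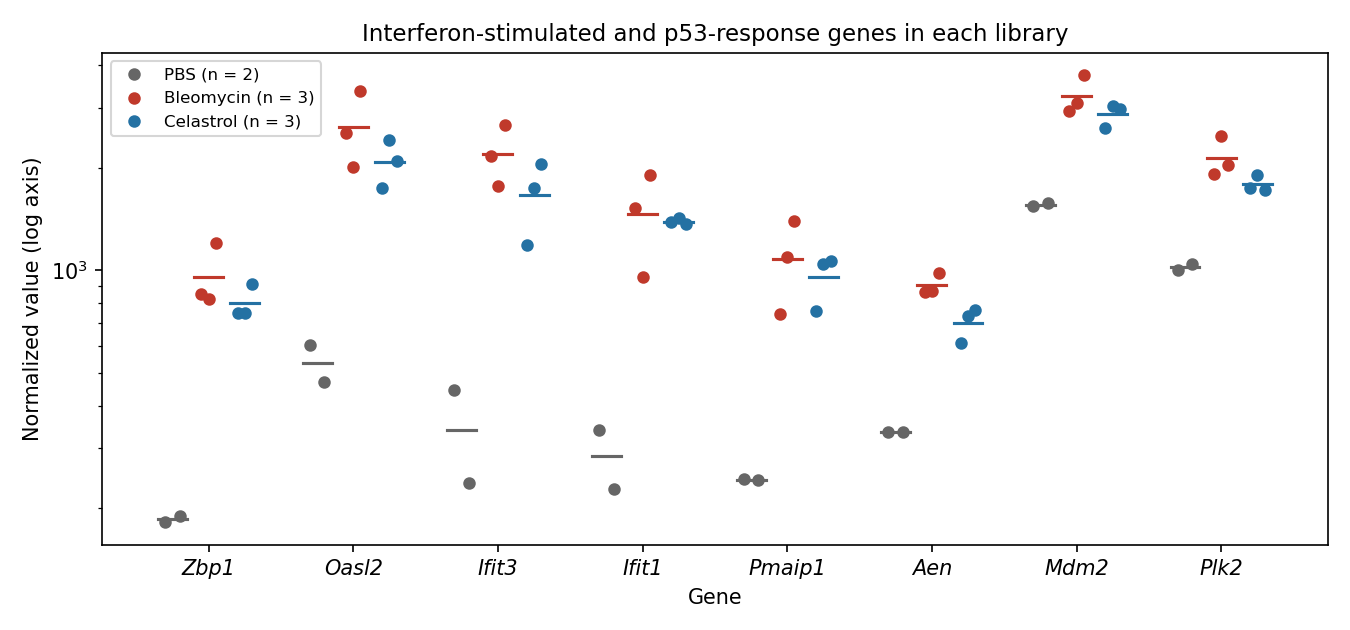
Normalized values (log axis) of 4 interferon-stimulated genes (Zbp1, Oasl2, Ifit3, Ifit1) and 4 p53-response genes (Pmaip1, Aen, Mdm2, Plk2) in each library, with points for libraries and short lines for group means. Zbp1 lay at 182 and 190 in the PBS libraries and at 822 to 1204 in the bleomycin libraries.

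Collagens moved the other way. Of 19 collagen genes, 0 rose, 3 fell and 16 did not pass, and 8 fell and 2 rose adjusted over the list alone. The median was -1.47 (camera adjusted p = 1.85e-08, and adjusted p = 0.257 with an estimated correlation). Col1a2 fell by 4.46 ± 0.76 (adjusted p = 0.031), Col3a1 of type III collagen by 3.59 ± 0.58 (adjusted p = 0.0274) and Col5a2 of type V collagen by 1.91 ± 0.33 (adjusted p = 0.031). Col1a1 had a log2 change of -4.91 ± 1.06 and did not pass (adjusted p = 0.079), with PBS libraries at 200815 and 48044 and bleomycin libraries at 18991, 1482 and 1238. Without PBS 2 the collagen median was -0.62. The median deviation of the collagens from their mean over libraries was 1.02 in Bleomycin 2 and 0.61 in PBS 3, so the groups overlapped.

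Other matrix lists were lower as well. In the matrix glycoprotein list 5 of 39 members fell, 0 rose and 34 did not pass, with 14 lower adjusted over the list alone (median -0.85, camera adjusted p = 7.13e-14, and adjusted p = 0.161 with an estimated correlation). Sparc, a collagen-binding matricellular protein, fell by 2.89 ± 0.37 (adjusted p = 0.0109), from 66714 ± 6282 (n = 2) to 9342 ± 3287 (n = 3). The small proteoglycan gene Lum fell by 2.28 ± 0.39, the fibrillin gene Fbn1 by 1.94 ± 0.33 and Cthrc1 by 4.74 ± 0.81, with adjusted p of 0.0307, 0.0317 and 0.031. In the collagen processing list 2 of 24 members fell and 22 did not pass, with 9 lower and 1 higher adjusted over the list alone (median -1.03, camera adjusted p = 1.4e-09, and adjusted p = 0.189 with an estimated correlation). The crosslinking enzyme genes Loxl2 and Lox fell by 1.93 ± 0.36 and 1.72 ± 0.33 (adjusted p = 0.0425 and 0.0493). In the protease and inhibitor list 2 of 28 members fell and 26 did not pass, with 9 lower and 4 higher adjusted over the list alone (median -0.35, camera adjusted p = 0.0218, and adjusted p = 0.257 with an estimated correlation). The collagen-degrading protease gene Ctsk fell by 2.55 ± 0.43 and Adamts12 by 1.13 ± 0.20 (adjusted p = 0.0307 and 0.0351). The protease list was not called without PBS 2 (median -0.07, adjusted p = 0.165) or without Celastrol 2 (adjusted p = 0.0711), and its median was -0.71 without PBS 3, where the glycoprotein median was -1.30.

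Markers of dermal fibroblasts were lower beside the matrix genes. Of 21 measured, 3 fell and 18 did not pass, and 8 fell adjusted over the list alone (median -1.41, camera adjusted p = 6.54e-13, and adjusted p = 0.13 with an estimated correlation). Dpt fell by 1.94 ± 0.32 (adjusted p = 0.0274), the transcription factor gene Prrx1 by 1.41 ± 0.23 (adjusted p = 0.0302) and Cd34 by 1.67 ± 0.29 (adjusted p = 0.0341), while Pdgfra had a change of -2.00 ± 0.39 (adjusted p = 0.0537). The Wnt and bone morphogenetic protein list was lower with 0 of 33 members past the threshold (median -0.81, camera adjusted p = 5.38e-07, and adjusted p = 0.21 with an estimated correlation), and Sfrp1 stood at -0.98 (adjusted p = 0.191).

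**Figure D2:**
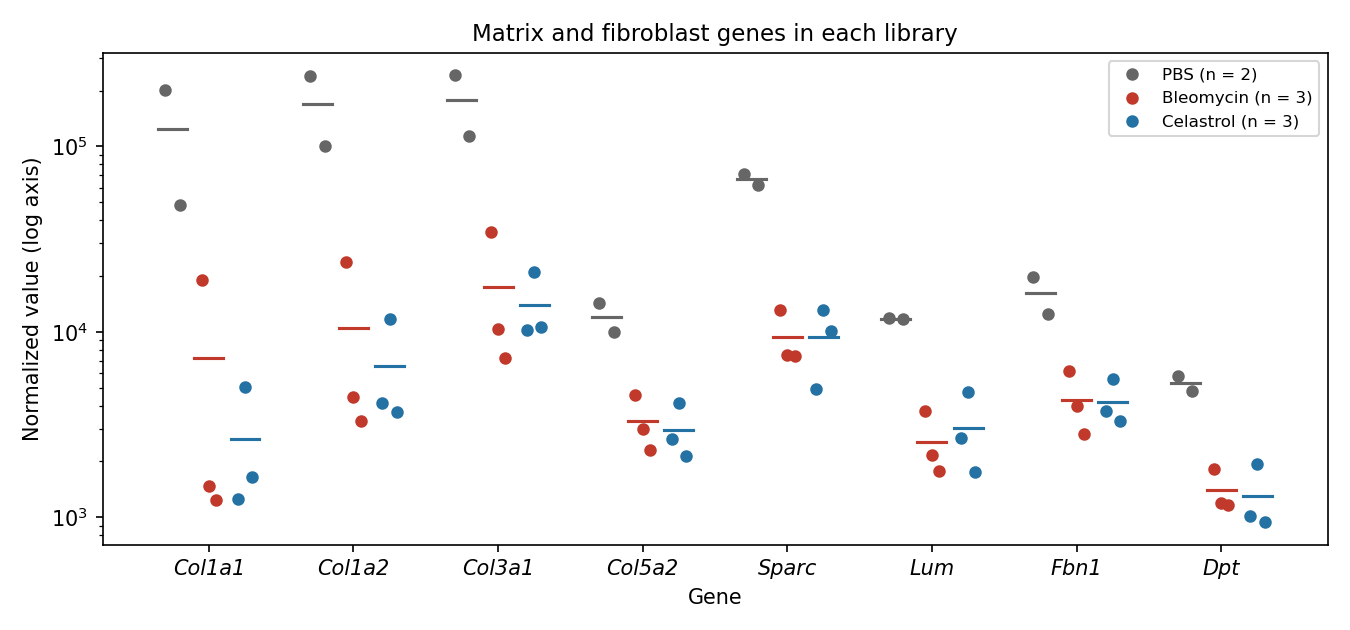
Normalized values (log axis) of 8 matrix and fibroblast genes in each library, with points for libraries and short lines for group means. Sparc lay at 62272 and 71156 in the PBS libraries, at 7380 to 13138 in the bleomycin libraries and at 4946 to 13110 in the celastrol libraries.

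Genes of the TGF-beta and contractile programmes that define fibrosis were not called in this comparison. In the TGF-beta list 0 of 27 members passed, with 1 higher adjusted over the list alone (median 0.02, camera adjusted p = 0.967), and in the myofibroblast list 0 of 26 (median 0.08, camera adjusted p = 0.452). Acta2, smooth muscle actin, stood at 0.42 ± 0.23 (adjusted p = 0.921), Ccn2, connective tissue growth factor, at 0.40 ± 0.33 (adjusted p = 1), Ccn1 at 0.76 (adjusted p = 1) and Tgfb1 at -0.05 (adjusted p = 1). With 1 library left out Ccn2 ranged from 0.06 to 0.74 and Tgfb1 from -0.34 to 0.24. Without Bleomycin 2 Acta2 stood at 0.27 and Ccn1 at 0.39. Of 26 YAP/TAZ targets 1 rose and 2 fell, with 1 higher and 3 lower adjusted over the list alone, and the list was not called (median -0.11, camera adjusted p = 0.121). The cardiac ankyrin repeat gene Ankrd1 rose by 3.86 ± 0.69 (adjusted p = 0.0351), and Fstl1 and Igfbp3 fell by 1.71 ± 0.25 and 1.69 ± 0.32 (adjusted p = 0.0204 and 0.0493).

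Myeloid genes were higher. In the macrophage list 2 of 30 members rose and 28 did not pass, with 14 higher and 2 lower adjusted over the list alone (median 0.78, camera adjusted p = 3.13e-09, and adjusted p = 0.21 with an estimated correlation). Chil3, a chitinase-like protein of alternatively activated macrophages, rose from 4.52 ± 6.39 (n = 2) to 388 ± 79.9 (n = 3), by 6.92 ± 0.83 (adjusted p = 0.00854), and the Fc receptor gene Fcgr1 rose by 4.05 ± 0.73 (adjusted p = 0.0366). Without PBS 3 Fcgr1 rose by 2.37 and did not pass (adjusted p = 0.0588). Of 11 neutrophil genes 2 rose, 1 fell and 8 did not pass, with 7 higher and 1 lower adjusted over the list alone (median 2.58, camera adjusted p = 3.54e-08, and adjusted p = 0.0628 with an estimated correlation). The alarmin gene S100a8 was 916 times higher (95% counting interval 164 to 36200, from about 1 read in PBS, adjusted p = 0.0366). Most of that ratio came from Bleomycin 3, since the bleomycin libraries lay at 38.6, 1610 and 80.8. Without Bleomycin 3 the S100a8 change was 5.45 where it had been 7.06, and it did not pass (adjusted p = 0.0533). Stfa2 rose by 4.19 ± 0.79 (adjusted p = 0.0471). The decoy receptor gene Il1r2 fell by 1.44 ± 0.28 (adjusted p = 0.0493). In the cytokine list 3 of 41 members rose and 38 did not pass, with 9 higher and 1 lower adjusted over the list alone (median 0.86, camera adjusted p = 1.32e-09, and adjusted p = 0.131 with an estimated correlation). The monocyte chemoattractants Ccl12 and Ccl2 rose by 5.34 ± 0.92 and 2.72 ± 0.51 (adjusted p = 0.0317 and 0.0425), and the acute-phase gene Saa3 by 3.90 ± 0.75 (adjusted p = 0.0493). The mast cell list had 0 of 12 members past the threshold (median 0.39, camera adjusted p = 0.0137, and adjusted p = 0.21 with an estimated correlation). Its call was lost without PBS 3 (median 0.15, adjusted p = 0.115) and without Bleomycin 3 (median 0.26, adjusted p = 0.105), and the macrophage median was 0.50 without PBS 3. The mast cell list was also not called without Bleomycin 3, Celastrol 2 and Celastrol 3 together (adjusted p = 0.185), a choice made after seeing the data.

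The epidermis and its appendages differed too. Of 16 genes of stressed or wounded epidermis 2 rose and 14 did not pass, with 10 higher and 1 lower adjusted over the list alone (median 2.25, camera adjusted p = 1.04e-12, and adjusted p = 0.13 with an estimated correlation). The antimicrobial lipocalin gene Lcn2 rose by 5.05 ± 0.69 (adjusted p = 0.0131), and Epgn, a ligand of the epidermal growth factor receptor, by 2.28 ± 0.44 (adjusted p = 0.0493). The wound keratin gene Krt6a stood at 3.25 ± 0.77 (adjusted p = 0.108). Sprr2a1, a precursor of the cornified envelope, rose from 4.27 ± 1.75 (n = 2) to 579 ± 317 (n = 3), by 6.65 ± 0.75 (adjusted p = 0.00532), in a family of near-identical genes whose shared reads leave the single members uncertain. Of 19 sebaceous gland genes 2 fell and 17 did not pass, with 9 lower and 1 higher adjusted over the list alone (median -1.03, camera adjusted p = 3.54e-08, and adjusted p = 0.0628 with an estimated correlation). The desaturase gene Scd3 fell by 2.62 ± 0.50 (adjusted p = 0.0468) and the lipid droplet gene Cidea by 1.70 ± 0.28 (adjusted p = 0.0274).

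Defb8, a beta-defensin gene, was at 923 ± 509 (n = 2) in PBS and at 0 in all 3 bleomycin libraries, at least 338-fold lower (adjusted p = 0.0111). Serpina3b fell by 2.69 ± 0.44 (adjusted p = 0.0274), and the other genes named by the rule among the lowest were Cyp2j12, Opcml, S100a7l2 and Tnmd, at -3.05, -3.05, -2.91 and -2.78. Among the highest, Gsdmc rose by 4.83 ± 0.81 (adjusted p = 0.0302) and Sprr2a3 was 143 times higher (95% counting interval 25.5 to 5690), while Adgrg7, Slc24a5 and Tmprss11d were at 0 in PBS and at least 35.8-fold, 22.3-fold and 25.7-fold higher. Adgrg7 and Tmprss11d were highest in Bleomycin 3, at 180 and 149, where the other bleomycin libraries lay between 19.3 and 90.4.

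Skeletal muscle genes were higher in bleomycin libraries beside all of these groups. Of 35 members 1 rose and 34 did not pass, with 6 higher adjusted over the list alone (median 0.63, camera adjusted p = 6.06e-10, and adjusted p = 0.328 with an estimated correlation). The list took 2.64% ± 0.0798 (n = 2) of all values in PBS and 4.41% ± 0.850 (n = 3) in bleomycin libraries. The myosin gene Myh1 rose by 1.31 ± 0.25 (adjusted p = 0.0499). Without Bleomycin 2 the muscle median was 0.39.

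Of the remaining lists, camera called 3. The oxidative phosphorylation list was higher with 0 of 41 members past the threshold (median 0.19, camera adjusted p = 0.00871, and adjusted p = 0.682 with an estimated correlation), with Uqcrb at 0.50 (adjusted p = 0.812). Of 27 immediate early genes 1 rose, with 5 higher adjusted over the list alone (median 0.80, camera adjusted p = 6.53e-06, and adjusted p = 0.357 with an estimated correlation), and of 16 glucocorticoid-responsive genes 2 rose, with 3 higher adjusted over the list alone (median 0.65, camera adjusted p = 6.25e-08, and adjusted p = 0.199 with an estimated correlation). Dusp1, a phosphatase that ends MAP kinase signalling and belongs to both lists, rose by 1.74 ± 0.30 (adjusted p = 0.0331). The lists of mitochondrially encoded genes (adjusted p = 0.101), differentiated epidermis (0.0637), basal epidermis (0.277), hair follicle (0.452), melanocytes (0.16), endothelium (0.452), adipocytes (0.967), nerve (0.913), blood (0.174), T and NK cells (0.367), B and plasma cells (0.343), dendritic cells (0.277), heat shock (0.121), NRF2 (0.307), unfolded protein response (0.366) and circadian clock (0.617) were not called. The median and the camera direction differed in sign for adipocytes, at 0.07 with a downward test, and for the unfolded protein response, at -0.00 with an upward test, and the endothelial median of 0.04 stood beside a mean of -0.01. In the dendritic cell list the median was 0.03 with a downward test. The oxidative phosphorylation call was lost without PBS 3 (median 0.03, adjusted p = 0.73) and without Bleomycin 2 (0.09, adjusted p = 0.15), and its median was 0.33 without PBS 2. Without PBS 3 the immediate early list (0.09, adjusted p = 0.143) and the cell cycle list (0.11, adjusted p = 0.0544) also lost their calls. Without Bleomycin 2 these medians were 0.33 and 0.65, the cell cycle median was 0.59 without PBS 2 and 0.08 without Bleomycin 3, and the glucocorticoid median was 1.03 without Bleomycin 3. Besides the collagens, median deviations per library overlapped between bleomycin and PBS for the called mast cell, cell cycle, oxidative phosphorylation and immediate early lists.

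The number of genes called rested on single libraries, with 70 called without PBS 2 (64 higher, 6 lower) and 18 without PBS 3 (18 higher, 0 lower). It was 33 without Bleomycin 3 (26 higher, 7 lower), 16 without Bleomycin 4 (15 higher, 1 lower) and 103 without Celastrol 5 (58 higher, 45 lower). In a fit of only the groups compared it was 46, and most of these were lower (20 higher, 26 lower). It was 711 with library weights (384 higher, 327 lower) and 17 with the replicate number as a block (11 higher, 6 lower). With 2 alternatives chosen after seeing the data it was 291, with a GC correction (177 higher, 114 lower), and 0, without Bleomycin 3, Celastrol 2 and Celastrol 3. Of the 51 named genes that passed, Sprr2a1 and Zbp1 passed in every fit with 1 library left out, 6 lost their call without Bleomycin 2, 44 without Bleomycin 3, 47 without Bleomycin 4, 21 without Celastrol 2, 10 without Celastrol 3 and 28 without Celastrol 5. Without PBS 2 and without PBS 3, 39 and 47 of the 50 tested lost it.

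**Figure D3:**
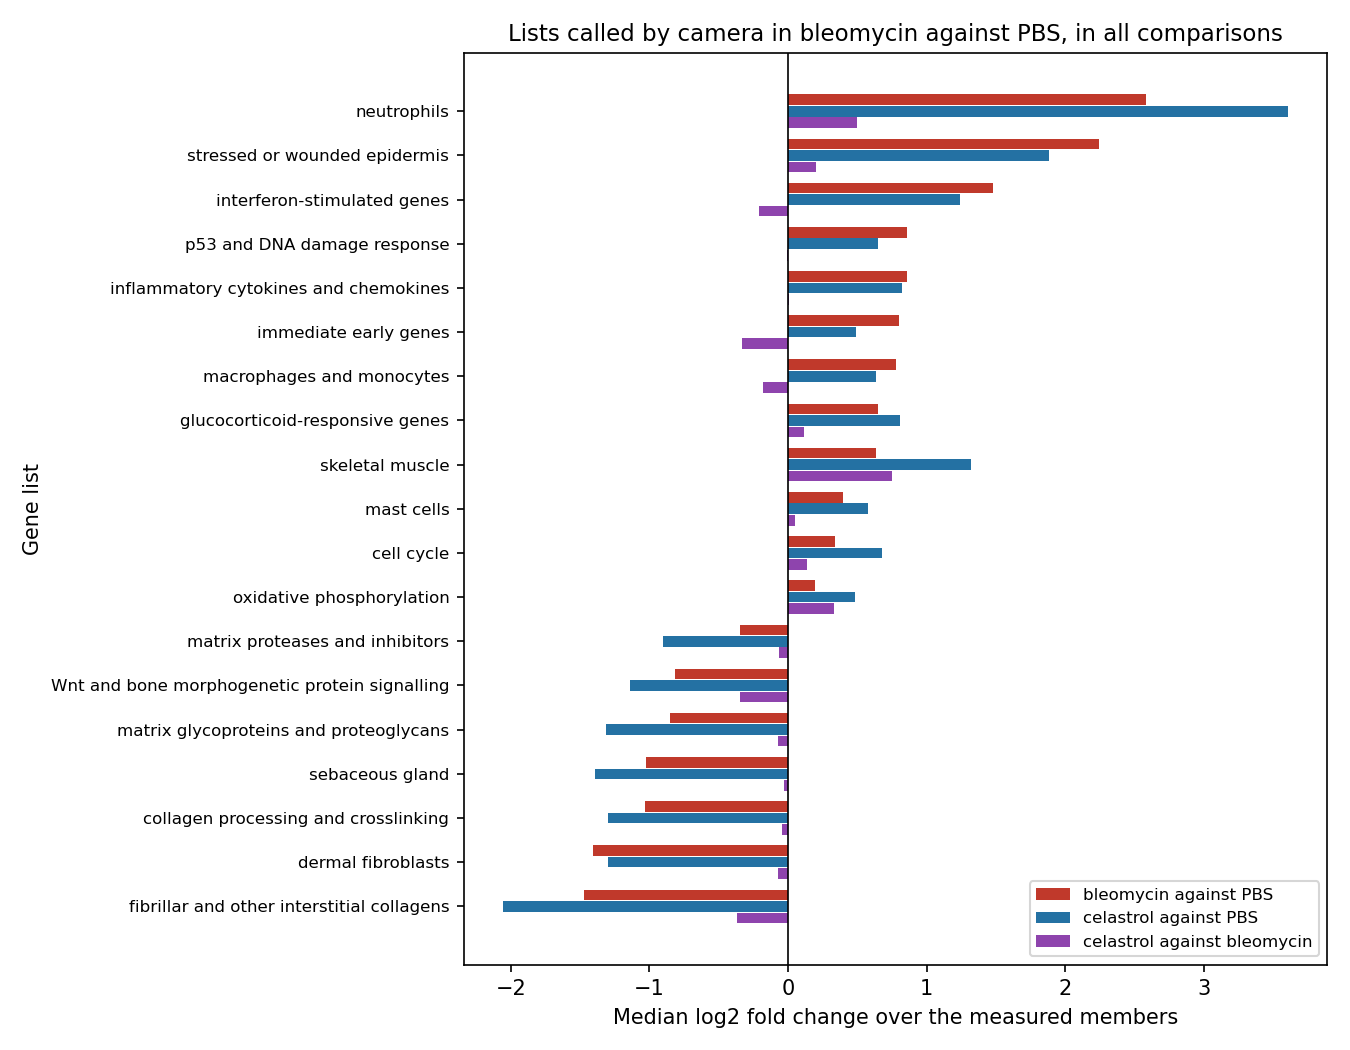
Median log2 fold change (horizontal axis) of the 19 gene lists that camera called in bleomycin against PBS, drawn for each of the 3 comparisons. The interferon list stood at 1.48 in bleomycin against PBS, at 1.24 in celastrol against PBS and at -0.21 in celastrol against bleomycin.

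The comparison of celastrol with bleomycin asked whether skin of celastrol mice differed from skin of bleomycin mice. No single gene passed in limma (0 of 23185, smallest adjusted p = 0.975), and 898 genes had an unadjusted p under 0.05 where chance gives 1159.2. In the simulated test of this comparison 66% of genes with a 4-fold change and 12% of genes with a 2-fold change were recovered. That test changed only genes with a mean value of at least 50, so genes with lower values were not covered. Collagen genes stood at -0.57 ± 0.95 for Col1a1 (95% interval -2.67 to 1.52), -0.32 ± 0.68 for Col1a2 (-1.83 to 1.19) and -0.06 ± 0.52 for Col3a1 (-1.22 to 1.09). Without Bleomycin 2 all 3 signs turned, with Col1a1, Col1a2 and Col3a1 at 0.70, 0.55 and 0.60. With each other library left out in turn, Col1a1 ranged from -1.27 to -0.17, Col1a2 from -0.87 to -0.02 and Col3a1 from -0.52 to 0.12. Acta2 stood at 0.25 ± 0.20 (95% interval -0.20 to 0.70), Ccn2 at -0.14 ± 0.30 (-0.80 to 0.51) and Ccn1 at -0.84 ± 0.53 (-2.02 to 0.34). Over the fits with 1 library left out, these ranged from 0.10 to 0.40 for Acta2, from -0.38 to 0.11 for Ccn2 and from -1.42 to -0.21 for Ccn1.

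Under the conditions of the naming rule, skeletal muscle genes were among those with the smallest p of genes higher in celastrol libraries. Myh4, a myosin of fast fibres, was at 128840 ± 8564 (n = 3) in celastrol and 63537 ± 12010 (n = 3) in bleomycin libraries, a difference of 1.03 ± 0.18 that did not pass (adjusted p = 0.975). The troponin genes Tnni2 and Tnnc2 stood at 1.07 and 1.17, the calcium-binding protein gene Casq1 at 1.20 and Ank1 at 2.12, and the other genes named by the rule were Trdn, Jph1, Ckmt2, Prkaa2 and Tpm1, at 0.80 to 1.11. In the muscle list 0 of 35 members passed over all genes and 16 were higher adjusted over the list alone (median 0.75, camera adjusted p = 7.78e-19, and adjusted p = 0.657 with an estimated correlation). The muscle list took 4.41% ± 0.850 (n = 3) of all values in bleomycin and 6.98% ± 1.30 (n = 3) in celastrol libraries. The list median was 0.48 without Celastrol 5. The median deviation of the members from their mean over libraries was 0.40 in Bleomycin 2 and 0.35 in Celastrol 3, so the groups overlapped.

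**Figure D4:**
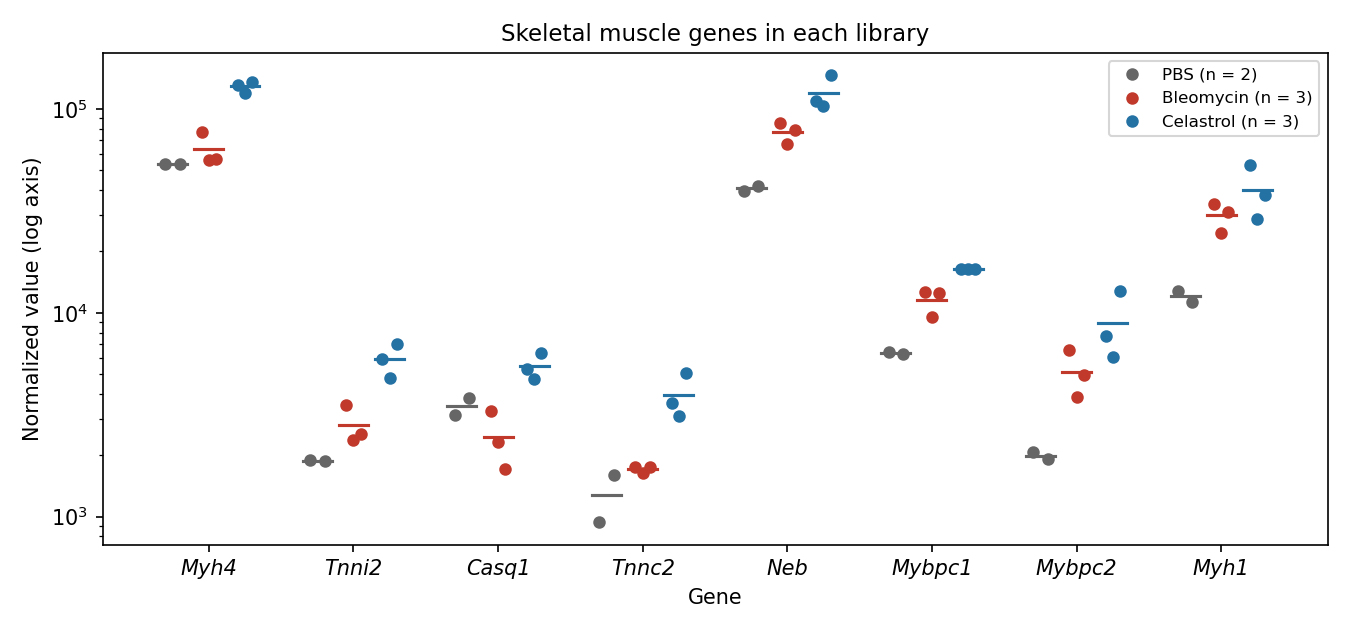
Normalized values (log axis) of 8 skeletal muscle genes in each library, with points for libraries and short lines for group means. Myh4 lay at 53460 and 53731 in the PBS libraries, at 56209 to 77403 in the bleomycin libraries and at 119264 to 135756 in the celastrol libraries.

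Lists of energy metabolism were called as higher as well, though their median deviations also overlapped between the libraries of both groups. Celastrol 5 had the highest median deviation in the muscle (1.00), oxidative phosphorylation (0.67) and mitochondrially encoded (0.79) lists. Whether the lists of energy metabolism differed apart from the muscle list was not tested. The 13 mitochondrially encoded genes all had positive changes and 0 passed (median 0.57, camera adjusted p = 3.69e-08, and adjusted p = 0.657 with an estimated correlation), with mt-Cytb at 0.62. In the oxidative phosphorylation list 39 of 41 members were positive and 0 passed (median 0.33, camera adjusted p = 3.75e-11, and adjusted p = 0.657 with an estimated correlation), with Cox6c at 0.54. In the differentiated epidermis list 25 of 33 members were positive and 0 passed (median 0.37, camera adjusted p = 1.26e-06, and adjusted p = 0.657 with an estimated correlation), with the cornified envelope gene Ivl at 0.77, Casp14 at 0.80 and the filaggrin gene Flg at 0.59. The heat shock list, which celastrol induces in cultured cells, had 19 of 26 positive members and 0 past the threshold (median 0.16, camera adjusted p = 0.00481, and adjusted p = 0.657 with an estimated correlation), with Ahsa1 at 0.38. The NRF2 list had a median of 0.15 (0 of 38 members, camera adjusted p = 0.0366, and adjusted p = 0.749 with an estimated correlation), with Gsta3 at 0.97 and Nqo1 at -0.95. The cell cycle list had a median of 0.13 (0 of 40 members, camera adjusted p = 0.0181, and adjusted p = 0.749 with an estimated correlation), with Ccnb2 at 1.42. Some of these genes moved by over 1.5 times with 1 library left out. Without Bleomycin 2 Ccnb2 stood at 0.70 and Casp14 at 0.52, without Bleomycin 3 Gsta3 stood at 0.63 and Nqo1 at -0.52, and without Celastrol 5 Cox6c stood at 0.36.

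Lists lower in celastrol than in bleomycin libraries included collagens. Of 19 collagens 18 had negative changes and 0 passed (median -0.37, camera adjusted p = 0.00481, and adjusted p = 0.744 with an estimated correlation), with Col8a2 at -1.87 and Col5a3 at -0.96. In the TGF-beta list 21 of 27 members were negative and 0 passed (median -0.35, camera adjusted p = 0.0181, and adjusted p = 0.657 with an estimated correlation), with Tgfb1 at -1.02 ± 0.43 (95% interval -1.97 to -0.06) and Bambi at -4.31. Bambi was at 0 in Celastrol 2 and Celastrol 3, the shallowest libraries, and at 14.2 in Celastrol 5. The size of its change therefore depends on the pseudocount. The interferon list had 34 of 39 negative members and 0 past the threshold (median -0.21, camera adjusted p = 0.00435, and adjusted p = 0.749 with an estimated correlation), with Stat2 at -0.44. The dendritic cell list had a median of -0.49 (0 of 18 members, camera adjusted p = 0.000777, and adjusted p = 0.657 with an estimated correlation), with Ciita, the activator of MHC class II genes, at -1.10 and H2-Eb1 at -0.46. The endothelial list had a median of -0.32 (0 of 21 members, camera adjusted p = 0.00481, and adjusted p = 0.744 with an estimated correlation), with Vwf at -0.58. The immediate early list had a median of -0.33 (0 of 27 members, camera adjusted p = 0.0181, and adjusted p = 0.749 with an estimated correlation), with Fos at -1.49. The Wnt and bone morphogenetic protein list had a median of -0.35 (0 of 33 members, camera adjusted p = 0.0181, and adjusted p = 0.744 with an estimated correlation), with Wif1 at -1.43 and Bmp4 at -1.21. Under the conditions of the naming rule, the genes with the smallest p among those lower in celastrol libraries were Ptpdc1 at -1.46, Ntrk2, Nnat at -4.93, Ciita, Igsf9, Pitpnm2, Ptk2b, Nfam1, Slc2a4rg-ps and the leptin gene Lep at -1.35, and none passed. Some of the changes named here shrank by over 1.5 times with 1 library left out. Without Celastrol 2 Tgfb1 stood at -0.57, Bmp4 at -0.68 and Nnat, which is at 0 in that library, at -3.04. Without Bleomycin 2 Vwf stood at -0.24 and Col5a3 at -0.45, and without Celastrol 5 Fos stood at -0.86.

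The other 24 lists were not called. These were matrix glycoproteins (adjusted p = 0.31), collagen processing (0.437), proteases (0.841), YAP/TAZ targets (0.322), myofibroblasts (0.31), dermal fibroblasts (0.988), macrophages (0.353), neutrophils (0.156), T and NK cells (0.153), B and plasma cells (0.349), mast cells (0.222), adipocytes (0.424), basal epidermis (0.988), stressed epidermis (0.213), hair follicle (0.542), sebaceous gland (0.841), melanocytes (0.639), nerve (0.903), blood (0.0722), cytokines (0.706), p53 (0.979), unfolded protein response (0.153), circadian clock (0.424) and glucocorticoid response (0.876). The sign of the median differed from the camera direction for myofibroblasts (-0.03), dermal fibroblasts (-0.08), basal epidermis (-0.02) and p53 targets (-0.01), all with an upward test, and for cytokines (0.01) with a downward test. The mean of the unfolded protein response list was -0.09 beside a median of 0.09, and that of the glucocorticoid list -0.04 beside 0.11. Adjusted over the list alone, 2 myofibroblast genes and 1 stressed epidermis gene were higher, and outside the muscle list no member of any other list passed.

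Median deviations per library overlapped between celastrol and bleomycin for every list called here except TGF-beta, dendritic cells and heat shock. An exact permutation of 3 against 3 libraries cannot give a p under 0.1, so it could call no list. Single libraries decided several of these list calls. Without Bleomycin 2 the collagen test turned upward (median -0.15, adjusted p = 0.978) and the cell cycle median turned to -0.01 (adjusted p = 0.917), so that both calls were lost. Without that library the TGF-beta (-0.16, adjusted p = 0.194), endothelial (-0.15, adjusted p = 0.286), immediate early (-0.05, adjusted p = 0.878) and Wnt (-0.08, adjusted p = 0.978) lists were not called either, and the mitochondrially encoded median was 0.30. Without Celastrol 5 the collagen (-0.32, adjusted p = 0.267), heat shock (0.10, adjusted p = 0.125), NRF2 (0.00, adjusted p = 0.789), immediate early (-0.33, adjusted p = 0.267) and Wnt (-0.08, adjusted p = 0.264) lists were not called, and the oxidative phosphorylation median was 0.14. Without Celastrol 3 the TGF-beta (-0.16, adjusted p = 0.0596), interferon (-0.17, adjusted p = 0.0719), cell cycle (0.12, adjusted p = 0.0719) and Wnt (-0.23, adjusted p = 0.0581) lists were not called. Without Bleomycin 4 the interferon (-0.05, adjusted p = 0.567) and NRF2 (0.08, adjusted p = 0.227) lists were not called. Without Celastrol 2 the endothelial (-0.25, adjusted p = 0.0652) and cell cycle (0.13, adjusted p = 0.246) lists were not called.

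Medians that moved by over 1.5 times with the call kept were those of collagens (-0.78 without Bleomycin 3, -0.87 without Bleomycin 4, -0.75 without Celastrol 3) and differentiated epidermis (0.62 without Bleomycin 3, 0.21 without Bleomycin 4). The interferon median was -0.44 without Bleomycin 3 and -0.33 without Celastrol 5, and the cell cycle median was 0.34 and 0.25 without these libraries. Without Celastrol 3 the NRF2, oxidative phosphorylation and immediate early medians were 0.24, 0.52 and -0.22, and without Celastrol 2 the dendritic cell median was -0.32.

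Other settings ended list calls in celastrol against bleomycin as well. With the replicate number as a block the differentiated epidermis (adjusted p = 0.241), interferon (0.102), heat shock (0.328) and NRF2 (0.691) lists were not called. NRF2 was also not called with a minimum of 50 (0.0666), TMM scaling (0.0557) or quantile normalization (0.169), nor the cell cycle with a minimum of 50 (0.0611) or heat shock with quantile normalization (0.199). Without PBS 2 and Bleomycin 2, a choice made after seeing the data, the collagen (0.815), TGF-beta (0.193), endothelial (0.226), cell cycle (0.832), immediate early (0.746) and Wnt (0.975) lists were not called. Without Bleomycin 3, Celastrol 2 and Celastrol 3, also chosen after seeing the data, a single celastrol library was left, so no list call is given. The medians of that library against bleomycin were -0.37 for TGF-beta, -0.18 for dendritic cells, -0.23 for interferon and 0.16 for the cell cycle.

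The genes that separate bleomycin from PBS were compared between celastrol and bleomycin libraries, with each gene set chosen without the bleomycin library it was compared with. The 200 highest genes, at 1.67 above PBS in the library left out of the choice, had a median difference between celastrol and that library of 0.05, with 3 values from -0.24 to 0.35. The 200 lowest genes, at -1.42 against PBS, had a median difference of -0.17, from -0.53 to 0.09. Over all 23185 genes the median difference between celastrol and the library left out was -0.063, from -0.080 to -0.032. The PBS libraries entered the choice of genes, so the distances from PBS of 1.67 and -1.42 are not held out and can be too large in size. Without Bleomycin 2, Bleomycin 3 and Bleomycin 4 the value for the highest genes was 0.08, -0.02 and 0.46, and without PBS 2, Celastrol 2 and Celastrol 5 it was 0.09, 0.12 and -0.02. For the lowest genes the sign turned without Bleomycin 2 (0.07) and without Celastrol 5 (0.07), and the value was -0.09 without PBS 2, -0.33 without PBS 3, -0.32 without Bleomycin 4 and -0.39 without Celastrol 3. The sets of genes were thus not shown to move either way under celastrol.

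The comparison of celastrol with PBS asked how skin of celastrol mice differed from control skin. Here 317 genes passed in limma, 191 higher and 126 lower, with a smallest adjusted p of 0.00021. Genes called as lower numbered 12 without PBS 2, 4 without PBS 3 and 14 without Celastrol 5. Many were the genes called for bleomycin. Both comparisons called 92 genes as higher and 49 as lower, against the same PBS libraries. Unchanged groups in 100 simulations shared 0.01 and 0.04 such genes on average, and independent lists of these sizes would share 0.865 and 0.283. Almost no gene is called where none is changed, so the simulated counts had to lie near 0. The values for independent lists leave out the shared PBS libraries. Neither reference can therefore test whether the overlap exceeds chance. The overlap was not measured with a separate PBS library for each comparison, so part of it can come from the shared libraries. The share of all genes with the same sign in both comparisons was 73.8%, where unchanged groups against the same PBS libraries gave 70.5% (69.7% to 71.1% over the simulations). The correlation of log2 fold changes across genes, which are not independent replicates, was 0.635, where unchanged groups gave 0.599 (0.580 to 0.614). The covariance was 0.706 against 0.530 simulated (0.498 to 0.558). Genes were drawn independently in these simulations, so the ranges leave out correlation between genes. They cannot show that the observed similarity exceeds chance.

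Matrix genes were lower in celastrol than in PBS libraries. Of 19 collagens 1 rose, 6 fell and 12 did not pass, with 14 lower and 2 higher adjusted over the list alone (median -2.06, camera adjusted p = 9.52e-10, and adjusted p = 0.211 with an estimated correlation). Col1a1 fell by 5.48 ± 1.06 (adjusted p = 0.0367), from 124430 ± 108000 (n = 2) to 2659 ± 2090 (n = 3), and Col1a2, Col3a1, Col5a1 and Col5a2 also fell, at -4.78, -3.65, -3.61 and -2.06. Of 39 matrix glycoprotein genes 6 fell and 33 did not pass, with 18 lower and 2 higher adjusted over the list alone (median -1.32, camera adjusted p = 2.46e-12, and adjusted p = 0.153 with an estimated correlation), with Sparc lower, at -2.94 ± 0.37 (adjusted p = 0.00645). In the collagen processing list 5 of 24 members fell, with 9 lower and 1 higher adjusted over the list alone (median -1.30, camera adjusted p = 1.1e-07, and adjusted p = 0.195 with an estimated correlation), among them Adamts2, which trims procollagen and fell by 2.81 (adjusted p = 0.0196), and Loxl4, which fell by 2.92 (adjusted p = 0.0403). In the protease list 1 of 28 members rose and 3 fell, with 9 lower and 4 higher adjusted over the list alone (median -0.90, camera adjusted p = 0.0226, and adjusted p = 0.233 with an estimated correlation), with the collagenase gene Mmp13 higher by 4.27 ± 0.83 (adjusted p = 0.0367) and the inhibitor gene Timp2 lower, at -2.41 ± 0.47 (adjusted p = 0.0367). Fibroblast markers were lower, with 3 of 21 past the threshold and 10 lower adjusted over the list alone (median -1.30, camera adjusted p = 2.88e-09, and adjusted p = 0.153 with an estimated correlation), and Dpt fell by 2.09 ± 0.32 (adjusted p = 0.0131). The Wnt list was lower with 0 of 33 members past the threshold and 9 lower adjusted over the list alone (median -1.14, camera adjusted p = 2.12e-08, and adjusted p = 0.153 with an estimated correlation). Of 26 YAP/TAZ targets 2 fell, Fstl1 and Igfbp3, at -1.61 and -2.00, with 2 lower and 1 higher adjusted over the list alone (median -0.15, camera adjusted p = 0.0392, and adjusted p = 0.347 with an estimated correlation). The complement gene C7, named by the rule, fell by 5.41 ± 1.05 and the carboxypeptidase gene Cpz by 4.31 ± 0.88 (adjusted p = 0.0367 and 0.0442).

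Interferon and p53 genes were higher in celastrol libraries too. Of 39 interferon-stimulated genes 14 rose and 25 did not pass, with 27 higher adjusted over the list alone (median 1.24, camera adjusted p = 1.62e-29, and adjusted p = 0.153 with an estimated correlation). Zbp1 rose by 2.10 ± 0.25 (adjusted p = 0.00494), and Ifit1, Ifit3 and Oasl2 rose by 2.31, 2.31 and 1.96. Of 30 p53 genes 8 rose and 22 did not pass, with 13 higher adjusted over the list alone (median 0.65, camera adjusted p = 1.06e-12, and adjusted p = 0.0173 with an estimated correlation). Ccng1, a cyclin gene that p53 activates, rose by 1.40 ± 0.18 (adjusted p = 0.00742), from 5646 ± 287 (n = 2) to 15096 ± 2821 (n = 3), and Pmaip1 rose by 1.96 ± 0.29 (adjusted p = 0.0125). In the cell cycle list Rrm1 rose by 0.94 (adjusted p = 0.0442) and 39 of 40 members did not pass, with 1 higher adjusted over the list alone (median 0.68, camera adjusted p = 4.71e-08, and adjusted p = 0.233 with an estimated correlation).

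Inflammatory and epidermal stress genes were higher as well. In the neutrophil list 4 of 11 members rose and 1 fell, with 6 higher and 1 lower adjusted over the list alone (median 3.61, camera adjusted p = 2.93e-07, and adjusted p = 0.121 with an estimated correlation), with S100a9 higher by 7.67 ± 1.44 (adjusted p = 0.0326) and S100a8 877 times higher (95% counting interval 157 to 34700). The low PBS values of most neutrophil genes limit the size of this median too. In the macrophage list 3 of 30 members rose and 1 fell, with 10 higher and 3 lower adjusted over the list alone (median 0.63, camera adjusted p = 8.03e-06, and adjusted p = 0.256 with an estimated correlation), with Chil3 higher by 7.26 ± 0.83 (adjusted p = 0.00483) and the lysozyme gene Lyz1 lower, at -3.42 ± 0.48 (adjusted p = 0.0106). In the cytokine list 5 of 41 members rose and 1 fell, with 10 higher and 1 lower adjusted over the list alone (median 0.82, camera adjusted p = 2.7e-06, and adjusted p = 0.179 with an estimated correlation), with the interferon-inducible chemokine gene Cxcl10 higher by 3.22 ± 0.59 (adjusted p = 0.0277) and Cxcl12 lower, at -1.39 ± 0.23 (adjusted p = 0.0196). Of 16 stressed epidermis genes 3 rose, with 10 higher adjusted over the list alone (median 1.88, camera adjusted p = 3.77e-11, and adjusted p = 0.153 with an estimated correlation), with Lcn2 higher by 5.46 and the wound keratins Krt16 and Krt6a by 4.94 and 3.82. Without PBS 3 Krt16 rose by 3.23 and did not pass (adjusted p = 0.259). In the differentiated epidermis list 2 of 33 members rose, with 6 higher and 1 lower adjusted over the list alone (median 0.54, camera adjusted p = 7.17e-06, and adjusted p = 0.25 with an estimated correlation), Flg by 2.40 ± 0.25 (adjusted p = 0.00379) and Casp14, a caspase of the cornified layer, by 1.95 ± 0.28 (adjusted p = 0.0107). Of 19 sebaceous gland genes 4 fell, with 11 lower and 2 higher adjusted over the list alone (median -1.39, camera adjusted p = 4.21e-06, and adjusted p = 0.129 with an estimated correlation), with Far2, which makes wax alcohols, down to 3554 ± 1739 (n = 3) from 14289 ± 984 (n = 2). Cstdc5, Sprr2a1 and Sprr2a2 rose by 8.50, 7.44 and 6.27, and Sprr2a3 was 404 times higher (95% counting interval 72.1 to 16000), in families of near-identical genes. Without PBS 3 the change of Cstdc5 was 4.505 and did not pass (adjusted p = 0.07). Tmprss11d, Adgrg7 and Slc24a5 were at least 45.6-fold, 42.7-fold and 27.6-fold higher, and Defb8 was at 0 in all 3 celastrol libraries, at least 229-fold lower. Serpina3b and S100a7l2 fell, at -3.53 and -3.70.

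Skeletal muscle genes were again higher beside these groups. Of 35 members 12 rose and 23 did not pass, with 18 higher adjusted over the list alone (median 1.32, camera adjusted p = 1.18e-23, and adjusted p = 0.153 with an estimated correlation). The list took 6.98% ± 1.30 (n = 3) of all values against 2.64% ± 0.0798 (n = 2) in PBS. Mybpc1, a myosin-binding protein of slow fibres, rose by 1.38 ± 0.17 (adjusted p = 0.00521), Tnni2 by 1.63 ± 0.22 (adjusted p = 0.0084) and the giant thin-filament gene Neb by 1.54 ± 0.22 (adjusted p = 0.0105). The lists of oxidative phosphorylation (0 of 41, median 0.48, camera adjusted p = 6.77e-11, and adjusted p = 0.25 with an estimated correlation) and mitochondrially encoded genes (0 of 13, median 0.79, camera adjusted p = 2.48e-07, and adjusted p = 0.233 with an estimated correlation) were higher as well. In the myofibroblast list Tpm1 and Tpm2, tropomyosins also made in muscle, rose by 0.97 and 1.24, and the list was not called (2 of 26 higher, and 2 adjusted over the list alone, median 0.01, camera adjusted p = 0.183).

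Further lists called were mast cells (0 of 12, median 0.57, camera adjusted p = 0.00229, and adjusted p = 0.153 with an estimated correlation), blood (0 of 9, median 1.14, camera adjusted p = 0.0125, and adjusted p = 0.305 with an estimated correlation), heat shock (0 of 26, median 0.27, camera adjusted p = 0.00109, and adjusted p = 0.153 with an estimated correlation) and NRF2 (0 of 38, median 0.14, camera adjusted p = 0.0182, and adjusted p = 0.443 with an estimated correlation). The immediate early list (0 of 27, median 0.49, camera adjusted p = 0.025, and adjusted p = 0.55 with an estimated correlation) and the glucocorticoid list (1 of 16, median 0.81, camera adjusted p = 4.26e-06, and adjusted p = 0.211 with an estimated correlation) were higher as well. The dendritic cell list was lower (1 of 18, median -1.004, camera adjusted p = 0.00154, and adjusted p = 0.277 with an estimated correlation), with the MHC class II gene H2-Eb1 down to 1133 ± 184 (n = 3) from 2581 ± 699 (n = 2) (adjusted p = 0.0345). Adjusted over the list alone, 6 dendritic cell genes were lower, and 1 heat shock gene and 3 glucocorticoid-responsive genes were higher. The lists of TGF-beta response (adjusted p = 0.122), T and NK cells (0.763), B and plasma cells (0.123), endothelium (0.205), adipocytes (0.469), basal epidermis (0.323), hair follicle (0.283), melanocytes (0.129), nerve (0.805), unfolded protein response (0.0524) and circadian clock (0.832) were not called. The circadian mean was -0.03 beside a median of 0.07. Ccn2 and Acta2 did not pass.

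The number of genes called was 104 without PBS 2 (92 higher, 12 lower), 38 without PBS 3 (34 higher, 4 lower) and 158 without Bleomycin 4 (100 higher, 58 lower). It was 143 without Celastrol 2 (102 higher, 41 lower) and 39 without Celastrol 5 (25 higher, 14 lower). Without Celastrol 3 it was 308, and most of these were lower (144 higher, 164 lower). It was 159 in a fit of only the groups compared (103 higher, 56 lower) and 41 with the replicate number as a block (30 higher, 11 lower). With alternatives chosen after seeing the data it was 511 with a GC correction (315 higher, 196 lower) and 150 without PBS 2 and Bleomycin 2 (123 higher, 27 lower). Without Bleomycin 3, Celastrol 2 and Celastrol 3, also chosen after seeing the data, Celastrol 5 was the only celastrol library, so no count is given. Of the 72 named genes that passed, Sprr2a1, Chil3, Lcn2, Flg and Zbp1 passed in every fit with 1 library left out, as did Defb8 where it was tested. Without Bleomycin 3, Bleomycin 4, Celastrol 2, Celastrol 3 and Celastrol 5, 10, 26, 38, 14 and 61 lost their call, and without PBS 2 and PBS 3, 45 and 64 of the 71 tested. Without PBS 3 the immediate early median turned to -0.16 (adjusted p = 0.829), and the YAP/TAZ (-0.24, adjusted p = 0.0696), blood (0.25, adjusted p = 0.29), heat shock (0.31, adjusted p = 0.0688) and NRF2 (-0.12, adjusted p = 0.694) lists were not called. Without PBS 2 the protease (-0.52, adjusted p = 0.127) and dendritic cell (-0.70, adjusted p = 0.0589) lists were not called. Without Celastrol 2 the protease (-0.53, adjusted p = 0.0795) and immediate early (0.44, adjusted p = 0.0723) lists, and without Celastrol 3 the YAP/TAZ (-0.28, adjusted p = 0.0533) and immediate early (0.42, adjusted p = 0.0769) lists, were not called. Without Celastrol 5 the YAP/TAZ (-0.16, adjusted p = 0.181), blood (0.92, adjusted p = 0.0639) and NRF2 (0.02, adjusted p = 0.316) lists were not called.

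Medians in celastrol against PBS that moved by over 1.5 times with the call kept did so mostly without a PBS library. Without PBS 2 they were -0.81 for collagen processing, -0.24 for YAP/TAZ targets, 2.03 for blood, 0.44 for NRF2, 0.74 for oxidative phosphorylation, 0.40 for mitochondrially encoded genes and 0.98 for immediate early genes. Without PBS 3 they were 0.37 for mast cells, 0.23 for differentiated epidermis, 0.44 for the cell cycle and 1.38 for mitochondrially encoded genes. Without Celastrol 2 they were -0.29 for YAP/TAZ targets, -0.57 for dendritic cells and 0.62 for blood. Without Celastrol 3 they were 1.80 for blood and 0.30 for NRF2, and without Celastrol 5 the oxidative phosphorylation median was 0.30. Median deviations per library overlapped between celastrol and PBS for the called blood, NRF2, immediate early and mitochondrially encoded lists.

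In celastrol against PBS the YAP/TAZ (adjusted p = 0.0743) and NRF2 (0.365) lists were not called with the replicate number as a block. With a minimum of 50 the YAP/TAZ (0.0578) and immediate early (0.0982) lists were not called, nor NRF2 with quantile normalization (0.0579). Without Bleomycin 3, Celastrol 2 and Celastrol 3, a choice made after seeing the data, a single celastrol library was left, so no list call is given. The medians of that library against PBS were 0.52 for mast cells, -0.51 for dendritic cells and 0.31 for immediate early genes.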

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

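With other pseudocounts, filters, scalings or a robust spread, the number of genes changed stayed within 1.5 times, at 140 to 223 for bleomycin against PBS and 288 to 372 for celastrol against PBS, and stayed at 0 for celastrol against bleomycin. List calls, 59 over the 3 comparisons, were lost with a minimum of 50 (4), TMM scaling (1) and quantile normalization (3), and 5 other lists gained a call with quantile normalization. With an estimated inter-gene correlation camera called 1, 0 and 1 lists in bleomycin against PBS, celastrol against bleomycin and celastrol against PBS, and fry called 4, 0 and 4. A fit of only the groups compared, which has fewer residual degrees of freedom, gave 46 and 159 genes for bleomycin and celastrol against PBS, and library weights gave 711 for bleomycin against PBS. Where not stated, the cause was not tested. The depth of the shallowest libraries, Celastrol 3 and Celastrol 2, limits genes with few reads.

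With the replicate number as a block, 17 genes changed in bleomycin against PBS and 41 in celastrol against PBS, and the NRF2 median in celastrol against bleomycin turned to -0.0422. The block ended 6 list calls and added 7. Deviations from group means correlated at 0.203 for PBS 2 with Bleomycin 2 and at 0.00725 for PBS 2 with Celastrol 2. For Bleomycin 2 with Celastrol 2 the value was -0.00485. It was 0.0964 for PBS 3 with Bleomycin 3, 0.111 for PBS 3 with Celastrol 3 and 0.0477 for Bleomycin 3 with Celastrol 3. Pairs with different numbers ranged from -0.203 (PBS 3 with Bleomycin 2) to 0.123 (PBS 2 with Celastrol 5). Deviations of the PBS libraries mirror each other, so the values are not independent and cannot settle whether the numbers pair the libraries.

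The next alternatives were chosen after seeing the data. A correction for GC content gave 291 genes for bleomycin against PBS and 511 for celastrol against PBS. Without PBS 2 and Bleomycin 2, whose deviations rose most with GC content, 150 genes changed in celastrol against PBS, and in celastrol against bleomycin the collagen and Wnt tests turned upward (medians -0.154 and -0.0553) and the cell cycle median turned to -0.00799. That fit ended 6 list calls and added 14. Without Bleomycin 3, Celastrol 2 and Celastrol 3, a single celastrol library was left, so no count of genes or list calls is given here. In that library Cd209b, Far2, Rptn and Serpinb6d, named after their values were seen, stood at -7.44, -3.20, 3.45 and -5.86 against PBS. In that fit the adipocyte median was 0.60 in bleomycin against PBS and 0.80 in celastrol against PBS. Against the remaining bleomycin libraries, the single celastrol library had medians of -0.61 for dermal fibroblasts, 0.37 for macrophages and 0.35 for adipocytes. Its medians were 0.35 for cytokines and -0.18 for glucocorticoid-responsive genes, and the held-out difference of the lowest genes was -0.56. These values rest on that library alone.

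With each library left out in turn, the genes changed ranged from 16 to 229 in bleomycin against PBS (without Bleomycin 4 and Bleomycin 2), from 0 to 1 in celastrol against bleomycin, and from 38 to 418 in celastrol against PBS (without PBS 3 and Bleomycin 2). The single gene in celastrol against bleomycin was Rptn without Bleomycin 3 (2.43, limma adjusted p = 0.00304) and Cd209b without Celastrol 3 (-6.69, limma adjusted p = 0.0351). Lists whose median or test direction turned included many without a call, such as mitochondrially encoded genes (-0.20 without PBS 2) and blood (-0.13 without PBS 3) in bleomycin against PBS. Over all settings in which lists were tested, medians ranged, among others, from -0.21 to 0.60 for adipocytes in bleomycin against PBS, from -0.99 to -0.15 for collagens (-0.87 without Bleomycin 4), from -0.00799 to 0.34 for the cell cycle and from -0.24 to 0.27 for glucocorticoid-responsive genes (0.18 without Bleomycin 2) in celastrol against bleomycin, and from -0.16 to 0.98 for immediate early genes and -0.12 to 0.48 for NRF2 in celastrol against PBS. Some lists that turned gained a call, among them dendritic cells in bleomycin against PBS without PBS 3 (-0.41) and, without Bleomycin 2, dermal fibroblasts (0.22) and myofibroblasts (0.16) in celastrol against bleomycin. The collagen medians kept their sign, and only the direction of the test turned, without Bleomycin 2. With 1 library left out the held-out difference ranged from -0.0167 to 0.46 for the highest genes and from -0.39 to 0.07 for the lowest. Fits without a PBS library assume that the lone PBS library varies like the other groups.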

Other observations

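The tests in this part were chosen only after the results they concern were seen. All genes in this paragraph were also chosen after their values were seen. Some members of multigene families induced by interferon were higher in bleomycin than in PBS libraries, and near-identical copies share reads and leave single members uncertain. Among Schlafen genes 4 of 7 rose and 3 did not pass, with Slfn1 at 3.86 ± 0.35 (adjusted p = 0.00186) and Slfn4 at 4.32 ± 0.39 (adjusted p = 0.00186). Among PYHIN genes, which include sensors of cytosolic DNA, 5 of 13 rose and 8 did not pass, with Ifi213 at 2.78 ± 0.25 (adjusted p = 0.00186). Ms4a4c, a membrane protein gene of myeloid cells, rose from 112 ± 35.6 (n = 2) to 1495 ± 491 (n = 3) (adjusted p = 0.00186). The interferon regulator gene Irf7 rose by 3.12. The lipid synthesis genes Elovl5 and Msmo1 fell by 1.73 and 1.48 (adjusted p = 0.0101 and 0.0209). The fibrosis-associated matrix gene Postn stood at 0.46 (adjusted p = 0.819) and the mesenchymal gene Vim at 0.01 (adjusted p = 1).

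Loci of satellite repeats, chosen after their values were seen, held the gene with the smallest p in bleomycin against PBS, Gm10719, at 4.37 ± 0.29 (adjusted p = 0.000399). Summed over 12 such loci, values were 212 ± 16 (n = 2) in PBS, 8295 ± 2480 (n = 3) in bleomycin and 8876 ± 957 (n = 3) in celastrol libraries. Gm10800 stood at 9.30 ± 1.03 (adjusted p = 0.00507) and Gm10801 at 4.72 ± 0.44 (adjusted p = 0.00186), and reads shared among such loci leave single members uncertain.

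For the lower collagens in bleomycin libraries, GC bias was not borne out, since the median was -1.41 after a GC correction and -1.47 before it. Dilution by the 35 listed muscle genes alone was not borne out, since the share left after them changed by -0.0266 on the log2 scale. Other RNA from muscle was not counted, so dilution by muscle RNA as a whole was not tested. A smaller share of dermal fibroblasts may contribute, since the fibroblast median minus the collagen median was 0.0644 (SE 0.384). Col1a2 and Col3a1, at -4.46 and -3.59, fell further than the fibroblast median of -1.41, which that share leaves open.

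For the higher muscle genes in celastrol than in bleomycin libraries, GC bias was not borne out, since the muscle median was 0.7485 after the GC correction and 0.7489 before it. More skeletal muscle tissue in the sample cannot be told apart from a change within the muscle. Of 27 abundant muscle genes, 96.3% had positive changes, but these are genes of the list whose rise is to be explained, so that test is void. Whether muscle entered at dissection or differed in the animals was not tested.

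For the satellite loci, reads moved only among the 12 loci were not borne out, since their sum was 39.2 times higher (SD 11.7) in bleomycin than in PBS libraries. The loci were chosen after their values were seen, and reads moved to or from copies outside them were not tested. GC bias was not borne out, since the median of the 12 loci was 5.07 after the correction and 5.02 before it. Genomic DNA in the libraries cannot be told apart from expression of the repeats. The sum of 637 olfactory and vomeronasal receptor genes was 0.988 times that in PBS. That test was judged void after its value was seen, because the SD of the receptor sum among bleomycin libraries, 22700, exceeds the rise of the summed loci, 8083.

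For the 0 genes called in celastrol against bleomycin, the 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The real split called 0 genes and the highest of the others called 0. With 0 in the real split 10 of 10 splits call as many, so the splits test nothing here.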
